A study of Mus musculus with 9 samples.

How the data were processed

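Gene expression was measured in bone marrow derived macrophages of C57BL6 mice on day 6 in vitro. Per the labels' protocols, cells were primed with 33 ng/mL LPS for 3 h and then exposed for 6 h to TMT OH (1.25 µM), TET Br (10 µM) or sterile saline, with 3 biological replicates per group and 9 arrays in all. The unit of the doses was taken from the series design. Also per the labels' protocols, total RNA was isolated with TRIzol, treated with DNase and passed over RNeasy columns, amplified with the Nugen WT-Ovation Pico system, labelled with biotin and hybridised to Affymetrix mouse genome expression arrays. Per the submitters' processing notes, the arrays were processed with RMA and affy, whose versions are not given in the sources used here.

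The deposited table held 45037 probe sets and 9 arrays in log2 units. No source names the base of the logarithm, and it was taken from the values, which ran from 2.05 to 14.8. The table was used as deposited, with no further normalization. It held 0 rows of the manufacturer's control probe sets, so a comparison of RNA quality between arrays by 3-prime and 5-prime controls could not be run, and the quantiles of each array were described instead. Array medians were 6.09 in saline, 6.11 under TMT and 6.17 under TET. No value gives the depth of an array, and the number of arrays limits the precision.

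Probe sets were named with the platform annotation. Of the 45037, 34945 named 1 gene, 932 named several and 9160 named none, and 204 carried a gene identifier not found in the reference annotation (GRCm38.p6), which was used only for names and neighbours. Probe sets naming several genes or none were left out of the gene tests. Each of 18193 genes was represented by its brightest probe set, and 9010 genes had several. Probe sets whose names mark them as able to bind related transcripts were kept. Of the genes named in the text, Aars, Flcn, Gar1, Hk3, Hspb1, Nfkbie, Spic, Suclg2, Trib3 and Tubb2a rested on such a probe set.

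Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 9 arrays (6 residual degrees of freedom), variances were moderated across genes without trend (prior degrees of freedom 3.99), and two-sided p-values were adjusted by Benjamini and Hochberg over 18193 genes in each comparison. Genes passed at an adjusted p under 0.05. The comparisons were TMT against saline, TET against saline and TET against TMT, and intervals of single genes are 95% intervals from the same model. SE of a fold change is the moderated standard error, whose median over genes was 0.121 in every comparison. The 3 groups share 1 estimate of the spread of each gene, so the SE of TMT against saline also carries the spread of the TET arrays.

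The gene lists, 44 in number with at least 5 measured members, covered inflammation, stress responses, metabolism, organelles, biosynthesis and markers of marrow cell types. They held 1056 distinct genes, of which 993 (94.0%) were measured, and the others were not analysed here. Lists were tested with camera of limma, which compares a list with all other genes, at a preset correlation of 0.01 and with adjustment over the 44 lists. Camera with a correlation estimated for each list and fry, which tests whether the genes of a list move on balance in 1 direction, were run beside it. Counts adjusted over the list alone adjust the p-values among the measured members only.

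The named genes followed a rule. For each comparison with saline it took the 12 largest rises and 12 largest falls among genes that passed, whose 3 treated arrays lay outside the saline range and whose mean in the higher group was at least the median over genes (6.82). For TET against TMT it took 8 of each. It added Nlrp3, Il1b, Casp1, Pycard, Il18, Gsdmd, Nek7, Tnf and Il6 in every comparison and up to 4 members of each list with the smallest adjusted p. Groups, comparisons, lists, tests, the naming rule and most alternatives were chosen before the data were examined.

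The overlap of the compounds was set against the product of the gene counts divided by 18193 and against 100 simulated data sets in which unchanged groups shared 3 control arrays. Alternatives to the main processing were leaving out each array in turn, keeping only genes at or above the median brightness (called bright genes alone), applying quantile normalization again, centring each array on its median, averaging over the probe sets of a gene, leaving out probe sets that may bind related transcripts, testing all probe sets, estimating array weights, trended robust moderation, no moderation, fitting the 6 arrays of each comparison alone, requiring a 1.5-fold change and testing against a 1.2-fold change. The alternative without moderation was a test with unequal variances on the 6 arrays of the 2 groups compared. It therefore also gave up the spread shared by the 3 groups, so its results do not show the effect of moderation alone. Cyclic loess between arrays, and quantile normalization again and centring for the lists, were added after seeing the data. The steps were tested on simulated data of 18193 genes, in which 38% of planted changes of 0.5 on the log2 scale were found, 92% of those of 1 and 100% of those of 2 and 3, with 11 false calls among 176 (6.25%). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.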

Results

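Bone marrow derived macrophages of C57BL6 mice were primed with lipopolysaccharide (LPS, a bacterial cell wall component that switches on inflammatory genes) at 33 ng/mL for 3 h. They were then given an organotin or sterile saline for 6 h. The organotins were TMT (trimethyltin hydroxide, 1.25 µM) and TET (triethyltin bromide, 10 µM), which carry methyl and ethyl groups on tin and were used at different doses. RNA of 3 biological replicates per group was read on 9 Affymetrix arrays, and 18193 genes were compared between groups of 3 arrays. The number of arrays limits the precision, and an exact permutation test of 3 arrays against 3 cannot give a p below 0.1. The p-values measure the spread between these samples, since no source used here says that the replicates came from separate mice. No value used here marks the background of the arrays, so a fold with 1 group near the low end of the signal range can understate the change. Values are log2 signals, differences between groups are log2 fold changes, and errors of single groups are SD with n = 3.

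The 3 groups of arrays lay apart from one another. The first principal component, with 60.4% of the variance, separated the TET arrays from the rest, and the second, with 27.4%, separated TMT from saline. Pearson correlations across genes, which are not independent replicates, were 0.997 within saline, 0.993 to 0.998 within TMT and 0.986 to 0.989 within TET. They were 0.973 to 0.978 between saline and TMT arrays and 0.945 to 0.949 between saline and TET arrays. The TET arrays had a narrower signal range, with an interquartile range of 3.51 ± 0.0489 against 3.86 ± 0.0275 in saline and 3.83 ± 0.0384 under TMT. No source used here says whether RMA was run on all 9 arrays together. Separate processing of the TET arrays was not excluded, and it would change the meaning of the TET counts and folds. The median SD of a gene within a group was 0.0907 in saline, 0.118 under TMT and 0.171 under TET. Across genes, the SD of the difference between TMT replicate 2 and the other TMT arrays was 0.271 and 0.312, against 0.185 between those 2.

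TMT against saline addressed which mRNAs of LPS-primed macrophages differ after exposure to this inducer of the NLRP3 inflammasome, the protein complex that activates caspase-1 and interleukin-1β. After TMT, mRNAs of LPS-induced inflammatory mediators, of cholesterol synthesis, of cell division and of ribosome assembly were lower, and mRNAs of the hypoxia response, autophagy and amino acid stress were higher. These list results rest on a preset correlation between genes, and with an estimated correlation 0 of 44 lists passed (lowest adjusted p 0.072). Tnf, encoding tumour necrosis factor, fell 2.72-fold (log2 fold change −1.45, SE 0.14, adjusted p = 2.8e-05), from 12.86 ± 0.11 to 11.41 ± 0.23. Il6, encoding interleukin-6, fell 2.41-fold (−1.27, SE 0.12, adjusted p = 2.6e-05). TMT changed 5049 of the 18193 genes (27.8%), of which 2608 rose and 2441 fell. At least 2-fold changes were 693 rises and 736 falls. At an unadjusted p under 0.05 the count was 6501. In 8129 genes (44.7%) the 3 TMT arrays did not overlap the 3 saline arrays, against 10% expected by chance. TMT changed 3971 genes without saline replicate 1, 4668 without TMT replicate 2, 8756 with array weights, 2945 without variance moderation and 2760 when tested against a 1.2-fold change. Here and below, the test without variance moderation also took a separate spread for each group. Centred on array medians, 2440 rose and 2574 fell. Every gene named below as risen or fallen in a comparison had 3 of 3 arrays of the compared group above or below the range of the other group.

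Nlrp3, the sensor of the inflammasome, was 11.81 ± 0.01 in saline and fell 1.31-fold under TMT (−0.39, SE 0.10, adjusted p = 0.013). That call was not kept without TMT replicate 3 (−0.32, adjusted p = 0.052) or without variance moderation (adjusted p = 0.14), and the adjusted p ranged from 0.00023 to 0.14 over its alternatives. Il18, encoding the cytokine interleukin-18 that caspase-1 matures, rose 1.35-fold (0.43, SE 0.08, adjusted p = 0.0016). Il1b, encoding interleukin-1β, did not pass (−0.20, SE 0.14, adjusted p = 0.37, lower in 2 of 3 arrays; −0.09 without TMT replicate 2). Casp1, encoding caspase-1, did not pass (0.16, SE 0.09, adjusted p = 0.26, higher in 3 of 3), nor did Pycard, encoding the adaptor ASC (−0.15, SE 0.08, adjusted p = 0.27, lower in 3 of 3). Nek7, encoding a kinase that binds NLRP3, did not pass (−0.20, SE 0.09, adjusted p = 0.16, lower in 2 of 3). With array weights, Casp1, Pycard and Nek7 passed (adjusted p = 0.0081, 0.027 and 0.0094, the lowest of their alternatives, whose highest were 0.51, 0.47 and 0.43). Gsdmd, encoding the pore protein gasdermin D, did not pass (0.33, SE 0.18, adjusted p = 0.25, higher in 2 of 3). Its adjusted p ranged from 0.0047 with array weights to 0.60 without TMT replicate 3 (0.19), and it passed without TMT replicate 2 (0.52, adjusted p = 0.046). Il6 missed the threshold without variance moderation (adjusted p = 0.057, the highest of its alternatives).

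**Figure D1:**
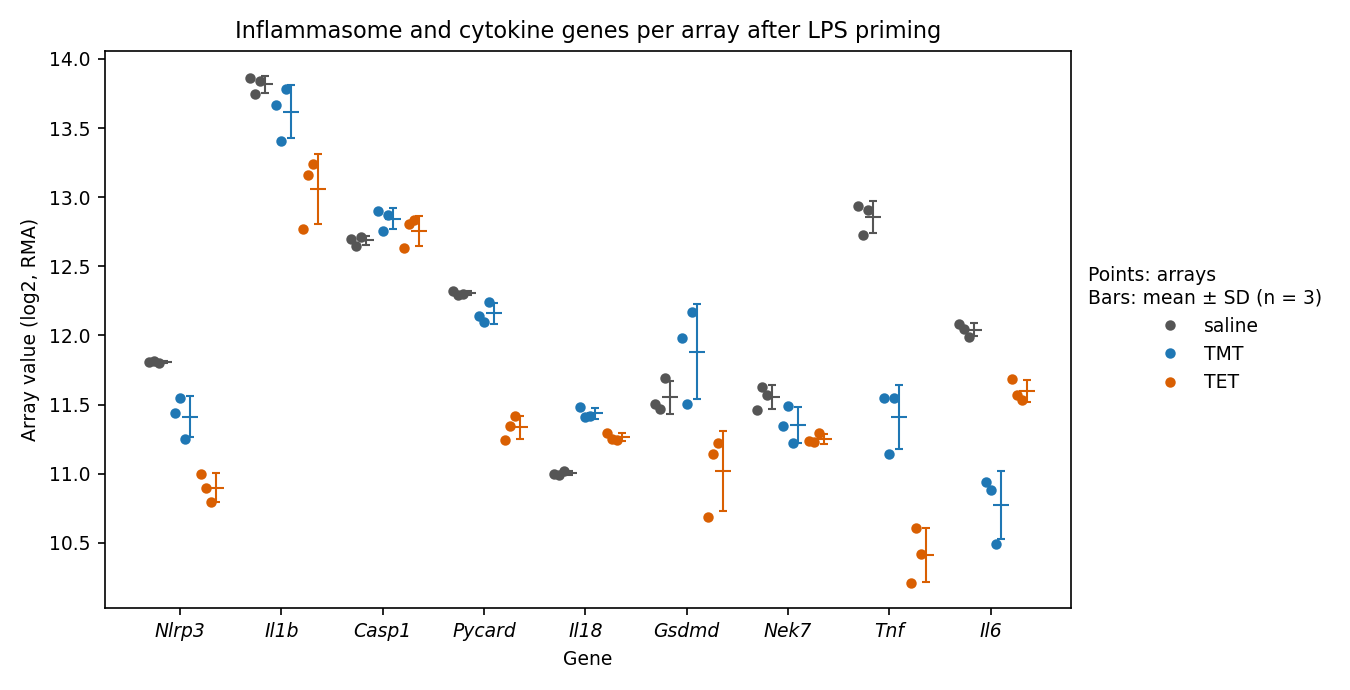
Log2 signal of the 9 genes fixed in advance in saline, TMT and TET macrophages, with 1 point per array and the mean ± SD (n = 3). Tnf lay at 12.86 in saline, 11.41 under TMT and 10.41 under TET, and Nlrp3 at 11.81, 11.41 and 10.90.

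Among the large falls under TMT, St6gal1, encoding a sialyltransferase, fell from 10.11 ± 0.19 to 5.07 ± 0.03, a level not shown to lie above background. The mean of the probe sets of St6gal1 fell by 3.25. Adamts4, encoding an aggrecan-cleaving protease, fell 19-fold, and Hpgd, encoding the enzyme that inactivates prostaglandins, fell 18-fold. Among secreted immune mediators, Il23a (a subunit of interleukin-23) fell 13.4-fold (−3.74, SE 0.27) and Tnfsf4 (the T cell costimulator OX40 ligand) 12-fold (−3.59, SE 0.16). Ifnb1 (interferon-β) fell from 7.91 ± 0.23 to 4.31 ± 0.39, within the range of the 3639 dimmest genes in saline (2.22 to 4.71), where signal was not shown to lie above background. Among the large rises was Irf2bp2, encoding a transcriptional corepressor (22.2-fold, 4.47, SE 0.22, adjusted p = 4e-07, with 4 of 4 probe sets risen). Hp, encoding the haemoglobin scavenger haptoglobin, rose 19.7-fold (4.30, SE 0.15), and Foxo3, encoding a stress-responsive transcription factor, 12.3-fold (3.62, SE 0.12). Spic, encoding a transcription factor of iron-recycling macrophages, rose 12.2-fold (3.61, SE 0.21) in a probe set that may bind related transcripts. Egln3, encoding an oxygen-dependent prolyl hydroxylase, rose 11-fold (3.46, SE 0.31). The adjusted p-values of these genes ran from 6.2e-08 (Foxo3) to 1.6e-05 (Egln3).

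Inflammatory gene groups were mostly lower after TMT. Of 29 measured LPS-induced cytokines and chemokines, 17 fell, 4 rose and 8 did not pass (17 and 4 adjusted over the list alone), with a median of −0.79. The list passed the set test (adjusted p = 2.65e-07, and adjusted p = 0.19 with an estimated correlation). Il12b, a subunit of interleukin-12, fell 5.79-fold (−2.53, SE 0.13), and Csf1, the macrophage growth factor, 4.85-fold (−2.28, SE 0.10). Of 25 NF-kB feedback and target genes, 16 fell and 2 rose (18 and 2 adjusted over the list alone; adjusted p = 1.8e-06, and adjusted p = 0.13 with an estimated correlation). Rel, encoding an NF-kB subunit, fell 4.52-fold (−2.17, SE 0.10), while Irak3, encoding an inhibitor of Toll-like receptor signalling, rose 3.43-fold (1.78, SE 0.11). Of 38 type I interferon response genes, 15 fell and 6 rose (17 and 6 adjusted over the list alone; median −0.15; adjusted p = 0.029, and adjusted p = 0.93 with an estimated correlation). Mx2, encoding an antiviral GTPase, fell 2.2-fold and Bst2, encoding tetherin, rose 1.86-fold. The interferon call was not kept without TMT replicate 2 (adjusted p = 0.25), with bright genes alone (0.15) or after cyclic loess (0.092). Of 19 alternative activation genes, 7 fell and 2 rose (8 and 2 adjusted over the list alone; adjusted p = 0.029, and adjusted p = 0.19 with an estimated correlation). Il10, encoding an anti-inflammatory cytokine, fell 6-fold (−2.59, SE 0.16) and Mrc1, encoding the mannose receptor, 2.36-fold (−1.24, SE 0.10). The alternative activation call was not kept without TMT replicate 2 (adjusted p = 0.090), with bright genes alone (0.29) or with the mean over probe sets (0.079).

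The 23 inflammasome genes did not pass the set test under TMT (9 rose, 3 fell; 12 and 3 adjusted over the list alone; adjusted p = 0.063, and adjusted p = 0.43 with an estimated correlation). They passed without TMT replicate 2 (adjusted p = 0.032), after cyclic loess (0.023) and after quantile normalization was applied again (0.022). Naip5, encoding a sensor of bacterial flagellin, rose 2.55-fold (1.35, SE 0.10) and Il18bp, encoding the binding protein that blocks interleukin-18, 2.14-fold (1.10, SE 0.09).

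Stress, hypoxia, glycolysis and autophagy groups were higher under TMT, and a zinc group was lower. Of 30 genes of the ATF4 integrated stress response, a programme switched on when amino acids or protein folding fail, 14 rose and 3 fell (15 and 4 adjusted over the list alone; adjusted p = 9.6e-04, and adjusted p = 0.13 with an estimated correlation). Trib3, a pseudokinase gene of this programme, rose 8.19-fold (3.03, SE 0.20), and Ddit3, encoding the transcription factor CHOP, 4.95-fold (2.31, SE 0.10). Of 24 hypoxia response genes, 17 rose and 4 fell (18 and 4 adjusted over the list alone; adjusted p = 7.0e-05, and adjusted p = 0.13 with an estimated correlation). Vegfa, encoding vascular endothelial growth factor, rose 3.78-fold (1.92, SE 0.12), and Bnip3, encoding a mitophagy receptor, 2.39-fold (1.26, SE 0.10). Of 18 glycolysis genes, 8 rose and 2 fell (8 and 3 adjusted over the list alone; adjusted p = 0.0085, and adjusted p = 0.70 with an estimated correlation), with Hk3, a hexokinase gene, up 2.07-fold. The glycolysis call was not kept with bright genes alone (adjusted p = 0.054). Of 24 autophagy genes, 14 rose and 1 fell (14 and 2 adjusted over the list alone; adjusted p = 0.0010, and adjusted p = 0.28 with an estimated correlation), among them Uvrag, 4.78-fold (2.26, SE 0.18), and the cargo receptor gene Nbr1, 2.6-fold (1.38, SE 0.09). Of 9 metallothionein and zinc genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 5.2e-04, and adjusted p = 0.13 with an estimated correlation). Most of those that fell encode zinc transporters, among them Slc30a4 (6.2-fold, −2.63, SE 0.13), and the metallothionein gene Mt2 fell 1.87-fold (−0.91, SE 0.08).

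Ribosome, cell cycle and cholesterol synthesis groups were lower under TMT, and proteasome and tubulin groups higher. Of 26 ribosome biogenesis genes, 22 fell and 0 rose (25 and 0 adjusted over the list alone), with a median of −0.71 (adjusted p = 7.75e-12, and adjusted p = 0.072 with an estimated correlation). Nop58, encoding a core protein of the small nucleolar particles that modify ribosomal RNA, fell 3.64-fold (−1.86, SE 0.09). Of 45 cytosolic ribosome genes, 16 fell and 0 rose (22 and 0 adjusted over the list alone; median −0.21; adjusted p = 7.4e-05, and adjusted p = 0.33 with an estimated correlation). Of 35 cell cycle genes, 18 fell and 2 rose (21 and 3 adjusted over the list alone; median −0.48; adjusted p = 1.8e-06, and adjusted p = 0.14 with an estimated correlation), with the centromere motor gene Cenpe down 2.58-fold (−1.37, SE 0.08). Of 20 cholesterol synthesis genes, 15 fell and 3 rose (17 and 3 adjusted over the list alone; adjusted p = 3.4e-06, and adjusted p = 0.072 with an estimated correlation). Cyp51, encoding lanosterol demethylase, fell 2.91-fold (−1.54, SE 0.12) and Sc5d, encoding a later enzyme of the pathway, 2.04-fold (−1.03, SE 0.08). Of 39 proteasome genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone; median 0.16; adjusted p = 0.0028, and adjusted p = 0.53 with an estimated correlation). Of 11 tubulins, 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.034, and adjusted p = 0.19 with an estimated correlation), with Tubb2a up 1.76-fold. The tubulin call was not kept without TMT replicate 1 (adjusted p = 0.055) or with the mean over probe sets (0.073).

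Of the 44 lists, 15 passed under TMT, 6 upward and 9 downward, and 0 passed with an estimated correlation (10 at an unadjusted p under 0.05, lowest adjusted p 0.072; limma's fry test passed 23). In the called lists of all comparisons the estimated-correlation p was the highest among the alternatives, apart from alternative activation under TMT (0.29 with bright genes alone), ribosome biogenesis under TET (0.45 with bright genes alone) and the mitochondrial ribosome after cyclic loess (0.86 under TET and 0.49 for TET against TMT).

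Other groups did not pass camera as a whole under TMT, though members changed. In the NRF2 and glutathione list of 27 genes, 7 rose and 8 fell (adjusted p = 0.98; the median of 0.12 and mean of 0.06 were positive and the test pointed down), and Hmox1, encoding heme oxygenase, rose 5.54-fold (2.47, SE 0.19). Of 14 LXR targets 4 rose and 3 fell (adjusted p = 0.82), with the cholesterol exporter genes Abca1 and Abcg1 up 3.09-fold and 3.73-fold. Among iron handling genes 5 of 15 rose and 5 fell (adjusted p = 0.55), with Lcn2, encoding a siderophore-binding protein, up 8.26-fold (3.05, SE 0.10). The heat shock response (4 of 20 rose, 2 fell, adjusted p = 0.82) and the ER unfolded protein response (7 of 27 rose, 4 fell, adjusted p = 0.53) did not pass. Nor did immediate early genes (7 of 30 rose, 11 fell, adjusted p = 0.54), p53 targets (8 of 21 rose, 7 fell, adjusted p = 0.92), BCL2 family and cell death regulators (8 of 20 rose, 5 fell, adjusted p = 0.82) or lysosome genes (8 of 28 rose, 9 fell, adjusted p = 0.82). The lysosome list had a median of −0.20 and a mean of 0.04. Against 27.8% of all genes, the changed members of mitochondrial lists were 3 of 35 for complex I, 5 of 24 for complexes II to IV, 2 of 16 for ATP synthase and 18 of 73 for the mitochondrial ribosome, 9 in each direction. For the TCA cycle 2 of 23 rose and 6 fell (adjusted p = 0.30), and the other adjusted p-values of these lists ran from 0.82 to 0.98.

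TET against saline addressed the same question for the ethyl compound at its higher dose. After TET, heat shock genes and ATF4 stress genes were higher, and LPS-induced mediators, unfolded protein response genes and cholesterol synthesis genes were lower. With an estimated correlation 0 of 44 lists passed (lowest adjusted p 0.235), and after cyclic loess the unfolded protein response (adjusted p = 0.095) and cholesterol synthesis (0.10) did not pass. Hspb1, encoding the small heat shock protein HSP25, rose 39-fold (log2 fold change 5.29, SE 0.10, adjusted p = 1e-09), from 6.28 ± 0.07 to 11.56 ± 0.18, in a probe set that may bind related transcripts; both of its probe sets rose. Chac1, encoding a glutathione-degrading enzyme of the ATF4 programme, rose 21.2-fold (4.41, SE 0.19). Tnf fell 5.44-fold (−2.44, SE 0.14, adjusted p = 4.3e-07). TET changed 9247 genes (50.8%), 4982 upward and 4265 downward, with 1212 rises and 1304 falls of at least 2-fold. TET changed 3927 genes without variance moderation and with a separate spread for each group, and 5143 when tested against a 1.2-fold change. With array weights it changed 8913, close to the 8756 under TMT. At an unadjusted p under 0.05 the count was 10396. In 10676 genes (58.7%) the groups did not overlap, against 10% by chance. Centred on array medians, 43.9% of the called genes rose, against 53.9% without centring. Among genes at or above the median brightness TET changed 6066, 2204 upward and 3862 downward. The median under TET was −0.33 in the 3638 genes at 7.82 to 9.88 in saline, and −0.24 in the 3639 brightest. After cyclic loess these were −0.07 and −0.06. A fall in a list of bright genes under TET may therefore be shared with bright genes in general.

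Inflammasome genes went both ways under TET. Nlrp3 fell 1.88-fold (−0.91, SE 0.10, adjusted p = 3.9e-05) and Pycard 1.96-fold (−0.97, SE 0.08, adjusted p = 8.5e-06, with 3 of 3 probe sets fallen). Il1b fell 1.69-fold (−0.76, SE 0.14, adjusted p = 0.0012), a call not kept without variance moderation (0.087, the highest of its alternatives). P2rx7, encoding the ATP-gated channel that triggers NLRP3, rose 8.61-fold (3.11, SE 0.17, adjusted p = 2.7e-07). Il6 fell 1.36-fold (−0.44, SE 0.12, adjusted p = 0.012), a call lost after cyclic loess (−0.26, adjusted p = 0.14, the highest of its alternatives). Il18 rose 1.2-fold (0.26, SE 0.08, adjusted p = 0.016). That call was lost with arrays centred on their medians (0.18, adjusted p = 0.078, the highest of its alternatives) and without saline replicate 1 (0.26, 0.051) or saline replicate 2 (0.26, 0.053), and the change was 0.46 after cyclic loess. Gsdmd fell 1.45-fold (−0.53, SE 0.18, adjusted p = 0.034), with an adjusted p from 0.014 to 0.15 over its alternatives. The call was lost without saline replicate 1, 2 or 3 (−0.56, −0.58 and −0.47), without TET replicate 1 (−0.37), after quantile normalization again (−0.42), after cyclic loess (−0.35) and without variance moderation. Nek7 fell 1.23-fold (−0.30, SE 0.09, adjusted p = 0.023), with an adjusted p from 0.0024 with the mean over probe sets (−0.48) to 0.42 after cyclic loess (−0.11). It was also lost without saline replicate 2 (−0.26) or 3 (−0.29), after quantile normalization again (−0.19) and without variance moderation (0.061). Casp1 did not pass (0.07, SE 0.09, adjusted p = 0.53), and its difference ran from −0.01 with centred arrays to 0.18 after cyclic loess. It was 0.13 without TET replicate 1 and 0.03 without TET replicate 3. Of the 23 inflammasome genes 7 rose and 11 fell (7 and 11 adjusted over the list alone), and the list did not pass (adjusted p = 0.37). After cyclic loess 8 rose and 8 fell, and the median of −0.18 became −0.10.

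Among the large rises under TET was 1700017B05Rik, an uncharacterised gene (64.7-fold, 6.02, SE 0.21; 3.25 as the mean of its probe sets). Cxcr4, encoding the receptor of the chemokine CXCL12, rose 35.8-fold (5.16, SE 0.10), from 7.87 ± 0.17 to 13.03 ± 0.08. Myh3, encoding an embryonic muscle myosin, rose 37.7-fold from 5.54 ± 0.17, a level not shown to lie above background. Mgam, encoding an intestinal maltase, rose from 3.37 ± 0.16 to 8.91 ± 0.44 and the uncharacterised gene 2010320O07Rik from 3.91 ± 0.12 to 9.95 ± 0.05. Ccnf, encoding cyclin F, rose from 4.79 ± 0.10 to 10.64 ± 0.25, and Hspa1l, encoding an HSP70 family chaperone, from 5.02 ± 0.12 to 10.41 ± 0.19. The saline levels of these 4 genes lay within or near the range of the 3639 dimmest genes (2.22 to 4.71) and were not shown to lie above background, so no fold is given. The largest fall was in Lpcat1, encoding a phospholipid acyltransferase (28.7-fold, −4.84, SE 0.24), and the mean of its 5 probe sets fell by 1.95. Dusp2, encoding a phosphatase of MAP kinases, fell 13.7-fold (−3.78, SE 0.13). Sema4c, encoding a semaphorin, fell 11.9-fold (−3.57, SE 0.29), and Gfi1, encoding a transcriptional repressor, 9.36-fold (−3.23, SE 0.14). Chil3, encoding a chitinase-like protein of alternatively activated macrophages, fell from 7.32 ± 0.25 to 4.06 ± 0.23, into the same range. The adjusted p-values of these genes ran from 1e-09 (Cxcr4) to 4.9e-06 (Sema4c).

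Heat shock and ATF4 groups rose under TET, on arrays with the narrower signal range given above. Of 20 heat shock response genes, 14 rose and 2 fell (14 and 2 adjusted over the list alone; median 0.75; adjusted p = 2.7e-04, and adjusted p = 0.35 with an estimated correlation). Hspa1a, encoding inducible HSP70, rose 12.7-fold (3.67, SE 0.10), Hsph1, encoding HSP105, 10.3-fold (3.36, SE 0.09) and the cochaperone gene Bag3 7.29-fold (2.87, SE 0.12). Of 30 ATF4 integrated stress response genes, 18 rose and 1 fell (18 and 1 adjusted over the list alone; median 0.73; adjusted p = 3.0e-04, and adjusted p = 0.235 with an estimated correlation), with Trib3 up 23.1-fold (4.53, SE 0.20) and Ddit3 7.99-fold (3.00, SE 0.10). In contrast, 17 of 27 ER unfolded protein response genes fell and 2 rose (17 and 2 adjusted over the list alone; median −0.37; adjusted p = 0.0016, and adjusted p = 0.39 with an estimated correlation). Sel1l, encoding a component of ER-associated degradation, fell 1.55-fold (−0.63, SE 0.09; −0.42 after cyclic loess), and Dnajb9, encoding an ER cochaperone, rose 4.02-fold (2.01, SE 0.10). The unfolded protein response call was not kept with bright genes alone (adjusted p = 0.14) or after cyclic loess (0.095), where 10 fell and 2 rose (median −0.17).

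**Figure D2:**
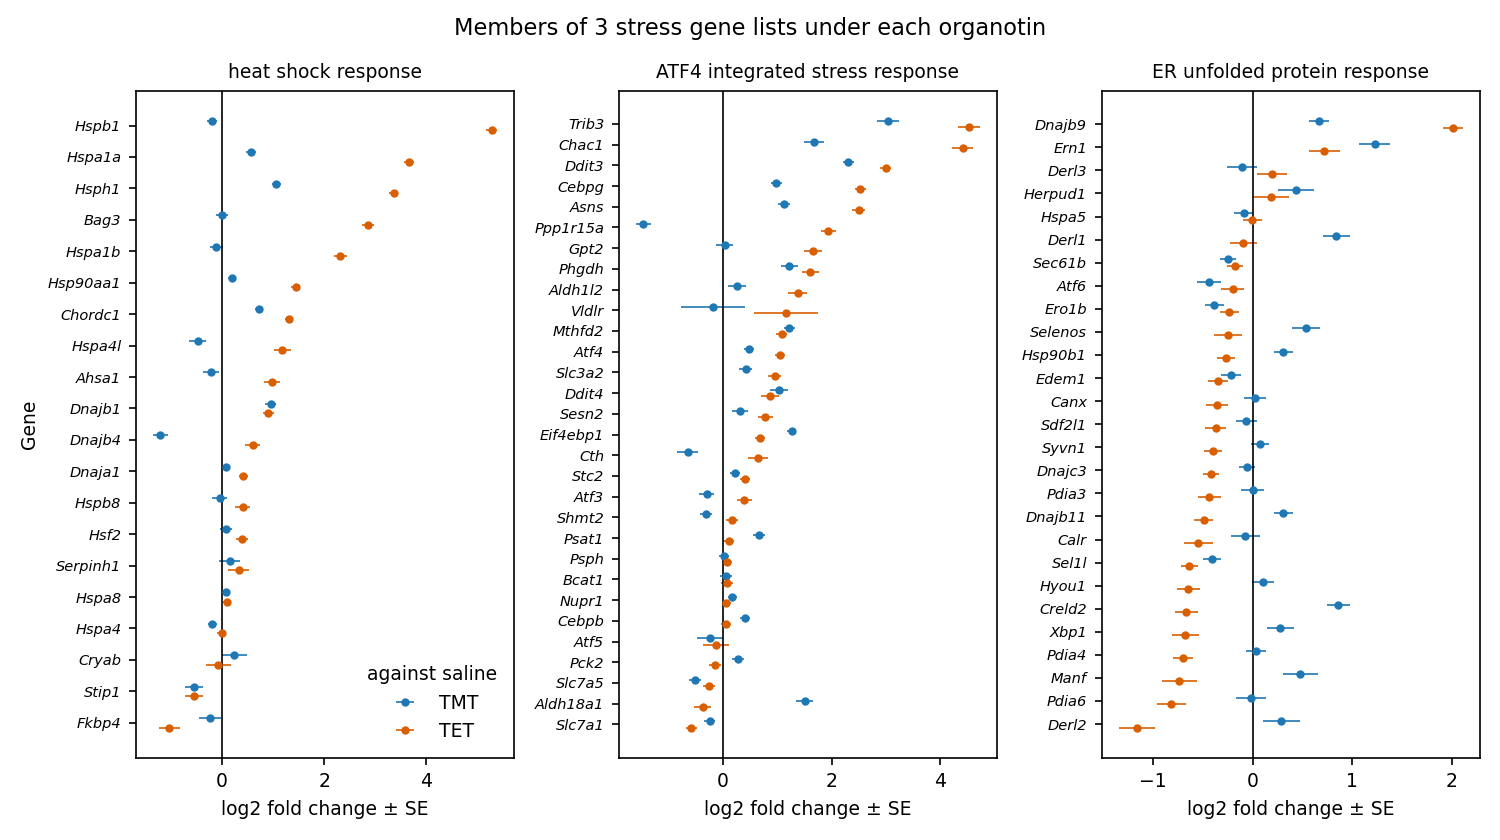
Log2 fold change against saline ± SE of each measured member of the heat shock (20), ATF4 (30) and ER unfolded protein response (27) lists under TMT and TET, from 3 arrays per group. Hspa1a rose by 3.67 and Chac1 by 4.41 under TET, while 17 of the 27 unfolded protein response genes fell under TET (10 after cyclic loess) and 4 under TMT.

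LPS-induced mediators and NF-kB targets fell under TET, on the same arrays with a narrower range. Of 29 LPS-induced cytokines and chemokines, 21 fell and 3 rose (21 and 3 adjusted over the list alone; median −0.49, and −0.30 after cyclic loess, where 18 fell and 4 rose; adjusted p = 5.4e-05, and adjusted p = 0.39 with an estimated correlation). Tnfsf9, encoding the costimulator 4-1BB ligand, fell 5.62-fold (−2.49, SE 0.09), while Osm, encoding oncostatin M, rose 5.99-fold (2.58, SE 0.11). Of 25 NF-kB feedback and target genes, 18 fell and 0 rose (18 and 0 adjusted over the list alone; median −0.50; adjusted p = 1.4e-05, and adjusted p = 0.235 with an estimated correlation), among them the inhibitor genes Nfkbie, 3.85-fold (−1.94, SE 0.12), and Nfkbia, 2.18-fold (−1.12, SE 0.08). The 38 type I interferon response genes did not pass as a list (9 rose, 13 fell, adjusted p = 0.39; after cyclic loess 13 rose and 10 fell; the median was 0.01 and the mean −0.10), although Irf1, an interferon regulatory factor gene, fell 4.18-fold (−2.06, SE 0.12). Alternative activation genes (4 of 19 rose, 5 fell, adjusted p = 0.44) did not pass.

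Metabolic and biosynthetic groups under TET included several calls that ended with the processing, again on arrays with the narrower signal range. Of 20 cholesterol synthesis genes, 11 fell and 2 rose (11 and 2 adjusted over the list alone; median −0.57, and −0.32 after cyclic loess; adjusted p = 0.0036, and adjusted p = 0.235 with an estimated correlation). Idi1, encoding isopentenyl diphosphate isomerase, fell 2.66-fold (−1.41, SE 0.12), and Nsdhl, encoding a sterol dehydrogenase, 2.24-fold (−1.17, SE 0.10). Of 23 TCA cycle and pyruvate dehydrogenase genes, 12 fell and 1 rose (12 and 1 adjusted over the list alone; median −0.49, and −0.22 after cyclic loess; adjusted p = 0.0024, and adjusted p = 0.39 with an estimated correlation). Suclg2, encoding a succinyl-CoA ligase subunit, fell 2.52-fold (−1.34, SE 0.16), a call not kept without variance moderation (0.056, the highest of its alternatives). Of 73 mitochondrial ribosome genes, 28 fell and 4 rose (27 and 3 adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.39 with an estimated correlation), and the median of −0.14 became 0.08 after cyclic loess, where 14 rose and 13 fell, and 0.00 after quantile normalization again. Mrpl28, a large subunit gene, fell 1.83-fold (−0.87, SE 0.09). Of 26 ribosome biogenesis genes, 12 fell and 3 rose (14 and 3 adjusted over the list alone; median −0.36, and −0.10 after cyclic loess; adjusted p = 0.0098, and adjusted p = 0.42 with an estimated correlation), with Gar1, encoding a small nucleolar particle protein, down 2.45-fold. With bright genes alone, these 4 lists did not pass (adjusted p = 0.23 for cholesterol synthesis, 0.15 for the TCA cycle, 0.41 for the mitochondrial ribosome and 0.45 for ribosome biogenesis). The same held after cyclic loess (0.10, 0.076, 0.86 and 0.38). After quantile normalization again, cholesterol synthesis (0.053), the mitochondrial ribosome (0.26) and ribosome biogenesis (0.12) did not pass.

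Lists that did not pass camera as a whole under TET held large single changes, on arrays with the narrower signal range. Of 24 autophagy genes 13 rose and 6 fell (adjusted p = 0.105), with Atg13, encoding a subunit of the kinase complex that starts autophagy, up 8.3-fold (3.05, SE 0.13). That list passed after cyclic loess (adjusted p = 0.0046), after quantile normalization again (0.015), with bright genes alone (0.014) and without TET replicate 1 (0.034). Of 30 immediate early genes 17 rose and 7 fell (adjusted p = 0.105; 0.012 after cyclic loess), with Fosl1 up 7.86-fold (2.97, SE 0.18) and Jun, which like Fosl1 encodes an AP-1 subunit, 4.04-fold (2.01, SE 0.10). Among p53 targets 10 of 21 rose and 7 fell (adjusted p = 0.63), with Gadd45a, a growth arrest gene, up 9.32-fold. Among BCL2 family and cell death regulators 7 of 20 rose and 7 fell (adjusted p = 0.49), with Pmaip1, encoding the death-promoting protein NOXA, up 10.4-fold. The iron exporter gene Slc40a1 rose 13.7-fold (3.78, SE 0.15) in the iron handling list (7 of 15 rose, 6 fell, adjusted p = 0.88, median −0.04 and mean 0.31). Flcn, encoding folliculin, a regulator of lysosomal nutrient signalling, rose 18-fold (4.17, SE 0.11) in the lysosome list (6 of 28 rose, 6 fell, adjusted p = 0.86; median −0.02 and mean 0.35; 9 rose and 4 fell after cyclic loess, median 0.08), and by 2.54 as the mean of its probe sets. Hypoxia response genes (6 of 24 rose, 10 fell, adjusted p = 0.54; median −0.09 and mean 0.07) and glycolysis genes (2 of 18 rose, 6 fell, adjusted p = 0.28) did not pass, nor did cell cycle genes (6 of 35 rose, 9 fell, adjusted p = 0.57; median −0.02 and mean 0.04). After cyclic loess 7 hypoxia genes rose and 7 fell (median 0.13), 3 glycolysis genes rose and 3 fell (0.00) and 9 cell cycle genes rose and 8 fell. Mitochondrial chaperones and proteases (5 of 19 rose, 9 fell, adjusted p = 0.60) had a median of −0.24, which was 0.04 after cyclic loess with 7 risen and 2 fallen, and a mean of 0.12. Of the 44 lists 9 passed under TET, 2 upward and 7 downward, and 0 with an estimated correlation (4 at an unadjusted p under 0.05, lowest adjusted p 0.235; fry passed 32).

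**Figure D3:**
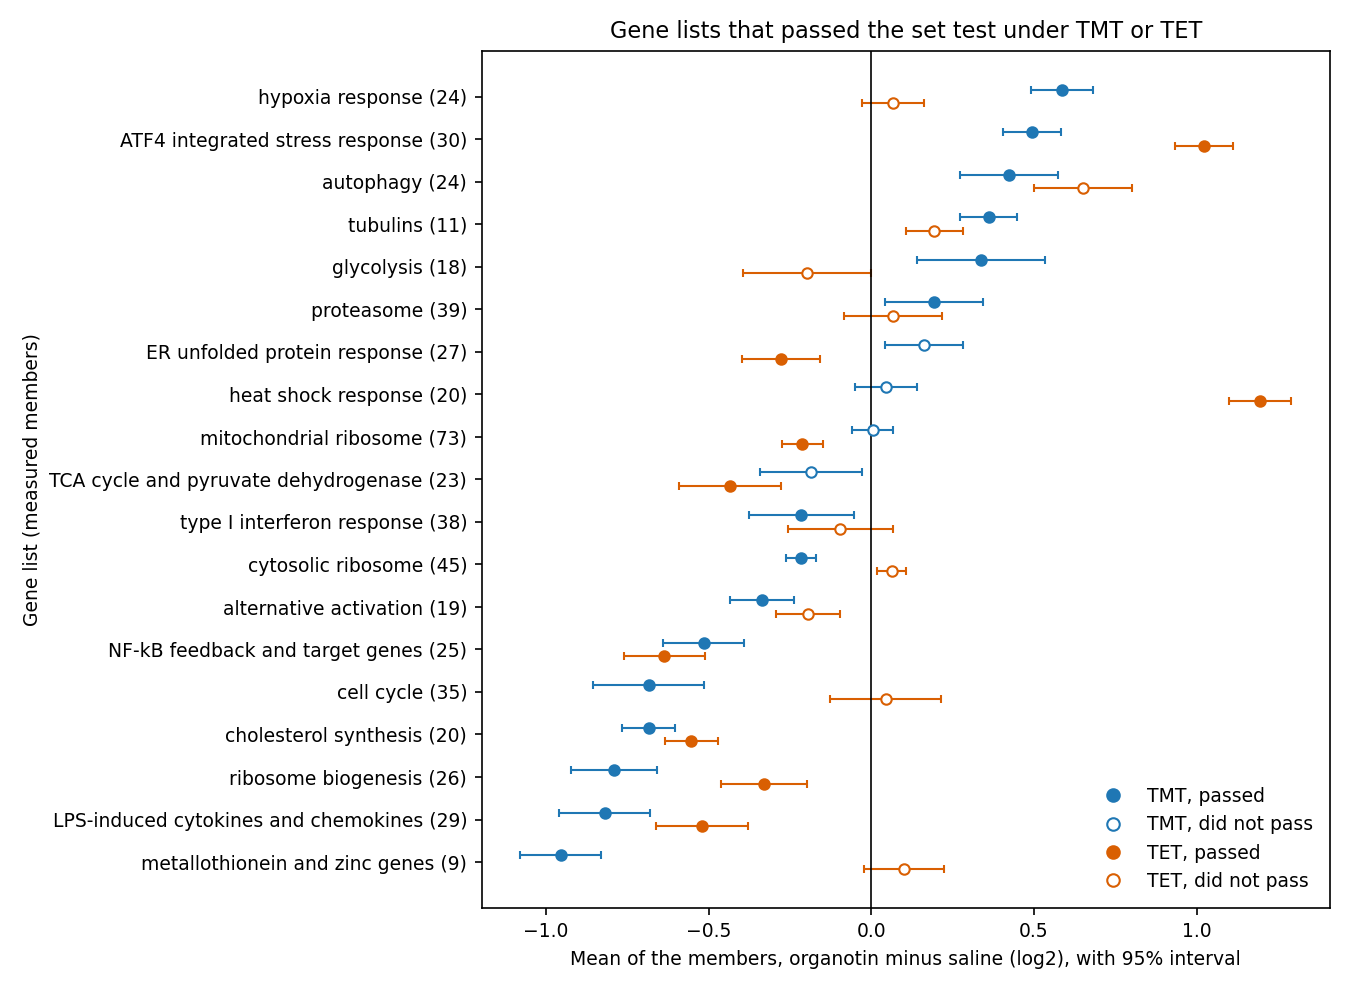
Mean log2 fold change of the members of the 19 lists that passed the set test under TMT or TET, with its 95% interval from 3 arrays per group. The interval comes from an unmoderated fit of the mean of each list per array. Filled points passed the set test, which compares a list with all other genes and is not what the interval measures. Ribosome biogenesis lay at −0.79 under TMT and −0.33 under TET, and the heat shock response at 1.19 under TET.

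TET was compared with TMT directly to ask where the methyl and ethyl compounds differ, at doses of 1.25 and 10 µM that were not matched. Hbegf, encoding a heparin-binding growth factor, was 51.9-fold higher under TET (log2 difference 5.70, SE 0.15, 95% interval 5.37 to 6.03, adjusted p = 7.4e-09). Its level was 6.74 in saline, 5.48 under TMT and 11.18 under TET, and the level under TMT was not shown to lie above background. Hspb1 was 44.6-fold higher under TET (5.48, 95% interval 5.25 to 5.71). Tor4a, encoding a torsin family ATPase, was 19.8-fold lower under TET (−4.31, 95% interval −4.62 to −3.99), and Siglece, encoding an inhibitory sialic acid receptor, 10.5-fold lower (−3.39, 95% interval −3.64 to −3.14, adjusted p = 1.9e-08). The compounds differed in 9425 genes (51.8%), of which 5115 were higher and 4310 lower under TET, and 10542 differed at an unadjusted p under 0.05. The balance turned with bright genes alone (2366 higher, 3904 lower), with centred arrays (4223 and 4599) and at a 1.5-fold change or more (2542 and 2998). Without variance moderation 3546 genes differed. In 10374 genes (57.0%) the TMT and TET arrays did not overlap, against 10% by chance.

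Among the genes fixed in advance, Tnf was lower under TET than under TMT by 1.00 on the log2 scale (95% interval −1.31 to −0.69, adjusted p = 0.00019), and Pycard differed by −0.82 (−1.01 to −0.64, adjusted p = 2.4e-05). Il6 was higher under TET (0.83, 0.56 to 1.10, adjusted p = 0.00027). Nlrp3 differed by −0.51 (−0.74 to −0.29, adjusted p = 0.0016), Il1b by −0.56 (−0.87 to −0.25, adjusted p = 0.0069) and Gsdmd by −0.86 (−1.27 to −0.45, adjusted p = 0.0030). Without variance moderation the adjusted p of Nlrp3 was 0.051, of Il1b 0.11, of Gsdmd 0.091 and of Il6 0.072, the highest of their alternatives. The compounds were not told apart by Casp1 (−0.09, 95% interval −0.28 to 0.11, adjusted p = 0.43) or Nek7 (−0.10, −0.31 to 0.11, adjusted p = 0.39). Casp1 differed by −0.06 without TMT replicate 1 and −0.02 without TET replicate 1 or after cyclic loess, and by −0.14 with centred arrays. Nek7 differed by −0.03 without TMT replicate 2, −0.16 without TMT replicate 3, −0.25 with the mean over probe sets, −0.04 after quantile normalization again and 0.05 after cyclic loess. Il18 did not pass (−0.17, 95% interval −0.34 to −0.00, adjusted p = 0.080). Its adjusted p ran from 0.029 with centred arrays (−0.23) to 0.86 after cyclic loess (−0.02), and it passed with array weights (0.043), with trended robust moderation (0.047) and without moderation (0.036).

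Gene groups also differed between the compounds in the set test, with the narrower signal range on the TET side. Of the 10 splits of the 6 arrays, 3, the real one included, passed as many lists as the real 11 (highest other 13). The other splits mix arrays of both compounds and keep part of their difference, so these are not counts by chance. With an estimated correlation 0 lists passed (lowest adjusted p 0.342). Heat shock genes were higher under TET in 12 of 20 and lower in 1 (13 and 1 adjusted over the list alone; median 0.52; adjusted p = 0.0013, and adjusted p = 0.34 with an estimated correlation), with Hspa1a 8.6-fold higher (3.10, SE 0.10). Of 27 unfolded protein response genes, 18 were lower and 1 higher (19 and 1 adjusted over the list alone; adjusted p = 0.0013, and adjusted p = 0.34 with an estimated correlation; 0.077 with bright genes alone), with Creld2, encoding an ER chaperone-like protein, 2.88-fold lower (−1.53, SE 0.11). Of 9 metallothionein and zinc genes, 7 were higher and 0 lower (7 and 0 adjusted over the list alone; adjusted p = 0.0032, and adjusted p = 0.34 with an estimated correlation), with the zinc importer gene Slc39a8 4.54-fold higher (2.18, SE 0.11). Inflammasome genes were lower in 14 of 23 and higher in 4 (15 and 4 adjusted over the list alone; adjusted p = 0.0062, and adjusted p = 0.34 with an estimated correlation; 0.25 with bright genes alone and 0.069 after cyclic loess), with Naip5 3.83-fold lower (−1.94, SE 0.10). Hypoxia response genes were lower in 14 of 24 and higher in 5 (15 and 5 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.34 with an estimated correlation; 0.075 with bright genes alone), with the prolyl hydroxylase gene Egln1 4.89-fold lower (−2.29, SE 0.09). Glycolysis genes were lower in 11 of 18 and higher in 1 (12 and 2 adjusted over the list alone; adjusted p = 0.0013, and adjusted p = 0.47 with an estimated correlation; 0.086 with bright genes alone), with the lactate exporter gene Slc16a3 3.88-fold lower (−1.96, SE 0.18).

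Cell cycle, cytosolic ribosome and early response groups lay higher under TET than under TMT, and the mitochondrial ribosome lower. Cell cycle genes were higher in 20 of 35 and lower in 1 (20 and 1 adjusted over the list alone; adjusted p = 0.0013, and adjusted p = 0.34 with an estimated correlation), with Cenpe 3.66-fold higher (1.87, SE 0.08). Cytosolic ribosome genes were higher in 28 of 45 and lower in 0 (29 and 0 adjusted over the list alone; median 0.28; adjusted p = 0.0022, and adjusted p = 0.47 with an estimated correlation), with Rps19 2-fold higher (1.00, SE 0.15). Immediate early genes were higher in 17 of 30 and lower in 5 (17 and 5 adjusted over the list alone; adjusted p = 0.030, and adjusted p = 0.47 with an estimated correlation), with Egr2, encoding an early response transcription factor, 4.28-fold higher (2.10, SE 0.12). That call was not kept without TET replicate 2 (adjusted p = 0.059) or 3 (0.054), and was stronger after cyclic loess (0.0025). Ribosome biogenesis genes were higher in 13 of 26 and lower in 4 (15 and 4 adjusted over the list alone; adjusted p = 0.048, and adjusted p = 0.47 with an estimated correlation), with Nop58 3.9-fold higher (1.96, SE 0.09). That call was not kept without saline replicate 1, 2 or 3 (0.051, 0.053 and 0.055), TMT replicate 1 (0.093) or TET replicate 2 or 3 (0.059 and 0.078), nor with the mean over probe sets (0.17). It was stronger after cyclic loess (adjusted p = 0.00067; 17 higher, 2 lower, median 0.63 against 0.42) and with bright genes alone (0.0017). Mitochondrial ribosome genes were lower in 32 of 73 and higher in 7 (32 and 7 adjusted over the list alone; median −0.22; adjusted p = 0.0021, and adjusted p = 0.34 with an estimated correlation), and did not pass after cyclic loess (0.49; 16 higher, 18 lower, median −0.03), after quantile normalization again (0.096) or with bright genes alone (0.34). Of the 44 lists 11 passed, 6 upward and 5 downward, and 0 with an estimated correlation (3 at an unadjusted p under 0.05, lowest adjusted p 0.342; fry passed 38).

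The overlap of the responses to TMT and TET was then examined. Both compounds changed 3483 genes, 2550 of them (73.2%) in the same direction and 933 in opposite directions. Both raised 1075 genes, against 714 expected from independent lists, and both lowered 1475, against 572. TMT raised and TET lowered 630, against 611, and TMT lowered and TET raised 303, against 668. Both comparisons used the same 3 saline arrays. In 100 simulated data sets with no change in either group, shared controls gave a covariance of the fold changes across genes of 0.0122, against 0.151 observed. The correlation across genes was 0.340. It was 0.50 in the simulations, a value that shared controls alone set where no gene changes. It is therefore no reference for data in which many genes change. The simulations called 0 genes under both compounds. Because 3 controls cannot be split into separate pairs, part of the excess of genes changed in the same direction may come from the shared saline arrays. Of the 2550 genes that moved alike, 1356 also differed between TET and TMT directly. Opposite genes numbered 611 without saline replicate 1, 597 without saline replicate 2 and 583 without saline replicate 3, and genes moving alike 1985 to 2034.

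Genes with opposite changes were chosen for naming after their values were seen. Pparg, encoding a lipid-sensing nuclear receptor, fell by 1.62 under TMT and rose by 1.89 under TET. Gem, encoding a small GTPase, fell by 2.74 and rose by 1.61, and Nedd4l, encoding a ubiquitin ligase, fell by 1.72 and rose by 1.88. Tor4a rose by 2.72 under TMT and changed by −1.59 under TET, Slc35c1, encoding a GDP-fucose transporter, by 1.47 and −1.79, and Ccnd3, encoding cyclin D3, by 1.46 and −1.82. The largest SE among these genes was 0.25 (Gem), and the highest adjusted p 0.00072 (Ccnd3 under TMT).

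**Figure D4:**
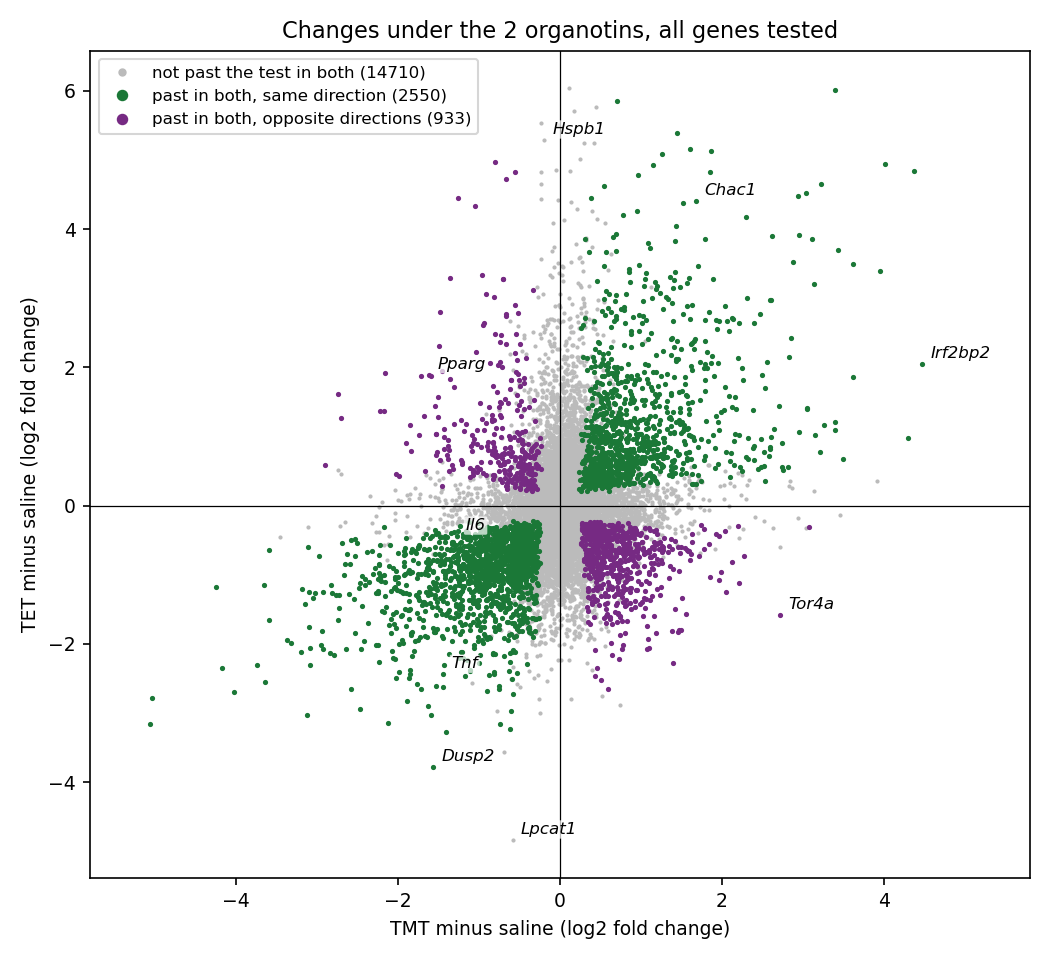
Log2 fold change under TMT (x) and TET (y) against the same 3 saline arrays for 18193 genes, 3 arrays per group, coloured by whether both changes passed and in which direction. Both compounds changed 2550 genes in the same direction and 933 in opposite directions, among them Tor4a and Pparg.

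Markers of other marrow cells did not pass camera at the preset correlation under either compound, and the values below are of that test. With fry, lymphocyte (adjusted p = 0.028) and erythroid markers (6.4e-05) passed under TMT. Under TET fry passed neutrophil (0.0082), dendritic cell (0.011), lymphocyte (0.00050), erythroid (8.2e-06) and mast cell markers (0.036) and macrophage identity genes (0.048). Under TMT, 4 of 13 neutrophil markers fell and 2 rose (adjusted p = 0.82), and under TET 4 fell and 1 rose (0.37), with S100a9, a calcium-binding protein of neutrophils, down by 1.70 and 1.66 on the log2 scale. Dendritic cell and MHC class II genes showed 2 rises and 1 fall of 13 under TMT (0.82) and 3 rises and 4 falls under TET (0.44), with the MHC class II gene H2-Eb1 down 2.27-fold under TET (−1.18, SE 0.10). Lymphocyte markers showed 1 rise and 2 falls of 13 under TMT (0.55) and 5 rises and 2 falls under TET (0.38). Erythroid markers showed 2 rises of 8 under TMT (0.15) and 5 under TET (0.16), mast cell and basophil markers 1 rise of 10 under each compound (0.92 and 0.44). Fibroblast and stromal markers showed 1 rise and 1 fall of 14 under TMT (0.98) and 7 rises and 1 fall under TET (0.37). Macrophage identity genes showed 7 rises and 4 falls of 22 under TMT (adjusted p = 0.98) and 3 rises and 10 falls under TET (0.16), with the fractalkine receptor gene Cx3cr1 down 6.43-fold under TET (−2.68, SE 0.12).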

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

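No test in this part was chosen before its result was seen. Probe sets with no gene name, which no comparison of the report used, also changed. Of 9160 such probe sets, 256 rose at least 2-fold under TMT and 628 under TET, and 169 and 639 fell. Changes of at least 2-fold were found in 4.64% of them under TMT and 13.8% under TET, against 7.77% and 16.3% of the probe sets naming 1 gene. At least 4-fold rises numbered 30 under TMT and 182 under TET. No explanation was tested for these probe sets. Groups of 3 arrays were not tested for arrays far from the others.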

How the results depend on the processing

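Results were recomputed under the alternatives named in the methods, of which cyclic loess, and renewed quantile normalization and centring for the lists, were chosen after seeing the data. The counts of changed genes, 5049 (TMT), 9247 (TET) and 9425 (TET against TMT), moved by over 1.5 times as follows. A 1.5-fold requirement gave 3180, 5383 and 5540, and testing against a 1.2-fold change 2760, 5143 and 5374. No moderation with unequal variances gave 2945, 3927 and 3546, and all probe sets 10335, 20915 and 20995. Array weights gave 8756 under TMT. Under TET they gave 8913, which moved less, so the counts of the 2 compounds were close with array weights. Bright genes alone gave 6066 under TET and 6270 for TET against TMT, where fewer genes were tested, and a covariance of the responses of 0.25. In these, 36.3% and 37.7% of the called genes rose. After cyclic loess the counts were 5102, 7730 and 8159, and 4887, 6780 and 7337 genes were called in the same direction as before. Leaving out 1 array gave 3971 to 5522, 7540 to 9372 and 8006 to 9232 genes, 14 to 15, 9 to 10 and 9 to 13 lists, and a covariance of 0.153 to 0.156 (saline arrays only). Without 1 saline array, 583 to 611 genes moved in opposite directions. With an estimated correlation 0, 0 and 0 lists passed, and with fry, which tests another hypothesis, 23, 32 and 38. Of results for named genes under an alternative, 11536 kept their side of the threshold, 297 no longer passed, 52 newly passed and 5 reversed. For lists these were 2078, 74, 80 and 3. A result counted as reversed only if its sign turned and it passed before or after. Results that passed neither time were counted as kept, even where the sign turned. Some alternatives change the test and not the fold change, so no direction of a gene could turn there. As the mean over probe sets, Mrpl1 was −0.23 for TET and −0.37 for TET against TMT, and Atpif1 −0.48 for TET against TMT. Without probe sets that may bind related transcripts, Derl1 was −0.0301 and Ighm 0.0166 under TMT. The fry direction was opposite to camera's under TET for mitochondrial chaperones and proteases (adjusted p = 0.0322), lysosome (0.00365) and iron handling (0.00339). For results that changed, the cause was not tested, other than fewer genes or arrays. Residuals of arrays with the same replicate number correlated at −0.148 to 0.308 and others at −0.302 to 0.262. These overlapping ranges gave no clear sign that replicate numbers pair the arrays, but with so few arrays they cannot exclude it. With a replicate block the counts were 4859, 8956 and 9119 genes and 15, 9 and 11 lists. Fitting the 6 arrays of each comparison alone, without the spread of the other group, gave 6075, 8610 and 8064 genes. With 3 arrays per group, 38% of planted changes of 0.5 were found in the simulation. It called 176 genes for TMT, against 5049 in the data. The adjusted threshold was therefore stricter in the simulation, and this share need not hold for the data.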

Other observations

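The tests of explanations and the counts over other splits in this part were chosen after the results were seen, and the list tests before. Gene groups not described above also held changes. V-ATPase genes, which encode the proton pump of lysosomes, rose in 9 of 22 and fell in 3 under TET (adjusted p = 0.14; 0.076 after cyclic loess, where 10 rose and 1 fell; 0.014 with bright genes alone), with the subunit gene Atp6v1h up 3.14-fold (1.65, SE 0.11), and rose in 3 and fell in 3 under TMT (0.92, median 0.11 and mean −0.03). Cytosolic aminoacyl-tRNA synthetase genes, which encode the enzymes that charge transfer RNAs, rose in 7 of 19 and fell in 2 under TET (adjusted p = 0.28, and 0.012 after cyclic loess) and rose in 4 and fell in 4 under TMT (0.98). Aars, the alanine enzyme gene, rose 3.47-fold under TET (SE 0.08). Among 21 PPAR targets and fatty acid oxidation genes, 9 rose and 4 fell under TET (0.28) and 5 rose and 4 fell under TMT (0.92, median −0.03 and mean 0.11), with Hilpda, encoding a lipid droplet protein, up 15.1-fold and 7.74-fold. Ion channels and pumps rose in 6 of 20 and fell in 5 under TMT (0.55) and rose in 5 and fell in 7 under TET (0.28, median −0.20 and mean 0.03). After cyclic loess 5 rose and 6 fell under TET, with a median of −0.0026.

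Mitochondrial gene groups did not pass camera at the preset correlation under TET other than those in the report, while fry passed complex I (adjusted p = 0.043), mitochondrial biogenesis (0.0033), mitochondrial dynamics (0.020) and mitochondrial chaperones (0.032, upward). Of 35 complex I genes 1 rose and 8 fell (adjusted p = 0.34), of 24 genes of complexes II to IV 3 rose and 4 fell (0.37) and of 16 ATP synthase genes 0 rose and 2 fell (0.44). After cyclic loess the counts were 6 and 3 (median −0.01 before and 0.08 after), 8 and 3 (−0.08 and 0.03) and 2 and 0 (−0.03 and 0.10). Of 18 mitochondrial biogenesis and mtDNA genes 4 rose and 8 fell under TET (0.16; 4 and 7 after cyclic loess, median −0.38 before and −0.17 after) and 3 rose and 5 fell under TMT (0.92). Ppargc1b, encoding a coactivator of mitochondrial genes, fell 5.31-fold under TMT (−2.41, SE 0.19), while Twnk, encoding the mitochondrial DNA helicase, rose 2.06-fold under TMT and 2.89-fold under TET. Of 18 mitochondrial dynamics and mitophagy genes 4 rose and 3 fell under TMT (0.92), and 4 rose and 6 fell under TET (0.44; 5 and 6 after cyclic loess, median −0.08 before and 0.10 after). Of 19 mitochondrial chaperones and proteases 2 rose and 2 fell under TMT (0.54), and under TET the matrix chaperonin gene Hspd1 rose 3.41-fold (1.77, SE 0.16).

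Many genes with low signal in saline rose under TET. Among genes below the median saline level (6.74), 589 rose at least 2-fold under TET and 187 under TMT. After cyclic loess, which removes an array-wide trend with brightness, 99.2% of the 589 still rose (median 1.64 before and 1.56 after). These genes were chosen for large rises, so nearly all were bound to stay raised. This share does not weigh against the narrower signal range as a cause. The median over all genes below that level was 0.21. Those of the 3639 dimmest genes and the next 3638 went from 0.18 to 0.03 and from 0.25 to 0.08. That of the following 3639 (5.97 to 7.82 in saline) went from 0.15 to 0.16. Those of the next 3638 and of the 3639 brightest went from −0.33 to −0.07 and from −0.24 to −0.06. The trend taken out of genes with low signal was smaller than the median rise of the 589. Because the 589 were chosen for rises of at least 2-fold, their median had to be that large. The comparison therefore does not settle whether the narrower range played a part. Cells of another marrow type stay open, since the highest share of markers raised at least 2-fold was 12.5%, between the bounds, in erythroid markers (1 of 8). Of these, 5 rose (median 0.49), and 4 after cyclic loess (0.36). Of 14 fibroblast and stromal markers 7 rose and 1 fell (median 0.31), and 5 and 1 after cyclic loess (0.19). Over all 71 markers of 6 types the share was 2.82%, against 6.66% of all genes. A further candidate explanation is transcription that runs on from raised neighbours, since 27.0% of the 589 had an adjacent gene raised at least 2-fold against a mean of 11.3% for random genes. This share lies between the bounds set for and against it. It counts a neighbour on either side, whatever its strand or distance, so it cannot tell run-on transcription from other clustering. A direct effect of TET stays open and untested.

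Genes raised at least 2-fold lay next to one another more often than random genes under both compounds. Under TET 28.2% had a raised neighbour against 12.8% for random genes, and under TMT 15.6% against 8.25%. The observed share was 2.21 times the random share under TET and 1.89 times under TMT, and the ratio of these was 1.17 (95% interval 0.903 to 1.60 from resampled blocks of 100 adjacent genes), so clustering specific to TET stays open. Shared regulation of neighbours, which could be a biological source, was not tested.

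Genes named Zfp with a number, which encode zinc finger proteins, went apart under the compounds. Of 305, 89 rose and 19 fell under TMT (median 0.23, against at most 0.07 in 10000 random sets) and 64 rose and 100 fell under TET (median −0.08, against at least 0.02), with Zfp266 at 1.07 and −2.08 (chosen after its values were seen). The median difference between TET and TMT was −0.36, and it was −0.34 after cyclic loess, which argues against an array-wide trend with brightness as the whole cause. It was also −0.34 without probe sets that may bind related transcripts. That step left 300 of the 305 genes, so it could hardly move the median and does not weigh against cross-binding. A difference between the compounds or doses may underlie the median difference and stays open as a hypothesis found and examined on the same data.

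The 6 arrays of a comparison have 10 splits into groups of 3, too few for a share under 0.05. Every other split mixes arrays of both groups, so their difference enters the spread within groups and few genes can pass. Such splits also keep part of the real difference, so their list counts are not counts by chance. The number of splits with at least as many genes as the real one, itself included, was 1 for TMT (5049, highest other 0), 1 for TET (9247, highest other 0) and 1 for TET against TMT (9425, highest other 0). For lists it was 1 for TMT (15, highest other 11), 1 for TET (9, highest other 7) and 3 for TET against TMT (11, highest other 13).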
